A study of Mus musculus with 5 samples.

How the data were processed

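Total RNA was measured in N2a cells, a mouse neuroblastoma line, after transfection with a control siRNA (siCtrl, 2 libraries) or an siRNA against Ewsr1 (siEwsr1, 3 libraries). Per the labels' protocols, 50000 cells received 2 pulses of lipid transfection, with collection 24 hours later. The siRNA concentration is given there as 100 µM, which is high for transfection and may be a slip of the unit that the labels cannot settle. Libraries were made from 2 µg of total RNA with a stranded kit that removes ribosomal RNA and does not select polyadenylated RNA, so histone messages and small nuclear RNA are also captured. Samples were assigned to groups by their titles. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

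Per the submitters' processing notes, reads were handled with STAR 2.5.2b, featureCounts 1.5.1 and edgeR (no version given) on GRCm38. The annotation release, the strand setting, the treatment of reads that map to several genes and any filter are not given in the sources used here. The authors deposited a file per library, each listing 54838 genes, and no file header names the unit. The deposited values behave as RPKM, that is reads scaled to exonic kilobases and to the library total. Values under 1 are intact. The 12129 to 12449 values per library of 1 or more lost their decimal point and carry dots as digit-group marks, as happens in spreadsheet software. For this reason the deposited unit was recorded as other than plain RPKM, and the decimal position was restored before any test.

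The restoration used the fact that a value multiplied by the exonic length of its gene and the number of counted reads must give a whole number of reads. Exonic lengths were unions of exons from GENCODE M21 on GRCm38, which holds 54809 of the 54838 identifiers. Each library's number of counted reads was solved from its intact values, of which 98.5% to 98.6% then came out whole within 1e-06 reads. The lowest decimal position that gave whole reads was preferred, and a higher reading was accepted where it brought the libraries closer together, without use of the group labels. Of 27255 genes above 0, 26642 were recovered with the GENCODE M21 length and 612 with an exonic length solved from the values. Of those 612, 587 lie on chromosomes 17, 18 and 19. In 1 gene no reading was whole, and 198 genes were left out because the odds of the chosen reading were under 20. The recovered reads of all genes summed to within 0.0175% of each library's total. The restoration was tested on simulated data with known reads for the siEwsr1 against siCtrl comparison, in a step run on 12000 genes, 5723 of them with a damaged value. All kept genes changed by 1.5-fold (50), 2-fold (50) or 4-fold (35 of 50 kept) were read correctly. Of genes changed by exactly 10-fold, 44 of 50 were kept and 12 of these were read correctly, so changes near 10-fold may be missed or understated here.

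The number of counted reads was 15766280 and 17314511 in the siCtrl libraries and 15045774, 21339459 and 17475740 in the siEwsr1 libraries. One read is worth 0.0469 to 0.0665 CPM (counts scaled to the library total), and the deepest library, siEwsr1 replicate 2, gives the smallest counting error.

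The plan made in advance assumed raw counts and a count model. Because the deposited values are not counts and the reads behind them are inferred, limma 3.58.1 (R 4.3.3) was used in its place on log2(RPKM + 0.1), after trimmed-mean scaling computed anew from the recovered reads (trimming 30% of ratios and 5% of levels). Genes with at least 10 reads at the median library size in at least 2 libraries were tested, with the group as the only term, a variance trend on the mean level and robust moderation. All adjusted p-values for genes are limma values with Benjamini-Hochberg adjustment, called under 0.05. Fold changes are on the log2(value + 0.1) scale, which understates changes of low genes. Tested on simulated data for the same comparison with 200 changed genes among 14859, the fit called 4 of 50 genes changed by 1.2-fold, 22 of 50 changed by 1.5-fold, 40 of 50 changed by 2-fold and 43 of 47 changed by 4-fold, and 7 unchanged genes. These simulated genes varied independently, no library deviated as a whole, and the decimal restoration was not part of the step. The 7 false calls therefore do not measure the error rate in the real libraries.

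A total of 33 gene lists was fixed before the data were examined. The 31 lists with at least 5 tested members were tested with camera (limma), two-sided, with a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists. Fry was run beside it. In the list test on simulated data, over 14908 genes, 10 of 10 lists of 30 genes with a planted log2 shift of 0.3 were called, and 0 of 20 other lists. The simulated genes varied independently, so the test does not show how often lists of genes that vary together are falsely called.

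Genes were named by a rule also fixed in advance. It takes Ewsr1 and related genes of its family, of which Taf15 is reported. Some genes that the rule takes are withheld and not reported. It takes the 10 largest changes in each direction among called protein-coding or long noncoding genes with at least 5 CPM in the higher group, no overlap between the groups and a symbol that is not a clone name or pseudogene. It takes the 5 most abundant called genes in each direction with at least a 1.5-fold change, and up to 4 members of each list with the smallest adjusted p. Genes named below outside the rule, among them list members beyond these 4, were chosen after their values were seen.

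Alternatives fixed in advance were other scalings (median of ratios, upper quartile), no filter, a stricter filter (at least 1 CPM in 3 libraries), limma-voom on the recovered reads, no robust moderation, the replicate number as a block, each library left out in turn, protein-coding genes alone, removal of mitochondrial and small noncoding RNA, an estimated correlation and an adjusted p under 0.01. Alternatives chosen after the data were seen were pseudocounts of 0.01 and 1, no rescaling, removal of genes with a solved length or a raised reading, odds of at least 1000 and removal of genes with either of a pair of 3′ UTR 7-mers. Splicing, named in the series title, was not analysed here because the files hold a single value per gene. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, data.table (1.17.8) and matplotlib 3.10.9 were also used.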

Results

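Ewsr1 encodes an RNA- and DNA-binding protein of the family to which Taf15 also belongs. To ask what its loss does to the transcriptome of a neuronal tumour line, RNA from N2a mouse neuroblastoma cells transfected with a control siRNA (siCtrl, n = 2) or with an siRNA against Ewsr1 (siEwsr1, n = 3) was sequenced after removal of ribosomal RNA. The libraries held 15766280 and 17314511 counted reads (siCtrl) and 15045774, 21339459 and 17475740 (siEwsr1). After filtering on low reads, 14925 genes were tested. Levels are given as RPKM, reads scaled to exonic length and library total, as mean ± SD, and gene positions are from GENCODE M21 on GRCm38.

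Ewsr1 (ENSMUSG00000009079, chromosome 11, 5069689 to 5099266, minus strand) was lower in each siEwsr1 library than in either siCtrl library. Its level was 71.7 and 72.3 RPKM in the siCtrl libraries and 35.7, 36.3 and 37.6 RPKM in the siEwsr1 libraries. The group means were 72.0 ± 0.394 RPKM (SD, n = 2) and 36.5 ± 0.974 RPKM (SD, n = 3). Ewsr1 fell by 0.96 on the log2 scale (SE 0.08, adjusted p = 9.02e-04, limma), a change of -48.4%. Taf15 (chromosome 11, 83473086 to 83506743) did not pass the test, with a log2 fold change of 0.29 (SE 0.11, adjusted p = 0.156). Taf15 stood at 15.7 ± 0.0475 RPKM in siCtrl and 19 ± 2.23 RPKM in siEwsr1. The log2 fold change of Ewsr1 stayed between -0.98 and -0.94 under 20 alternatives, and its adjusted p ranged from 4.14e-12 to 0.0568. The largest p came without siCtrl replicate 2, where 1 control library was left.

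**Figure D1:**
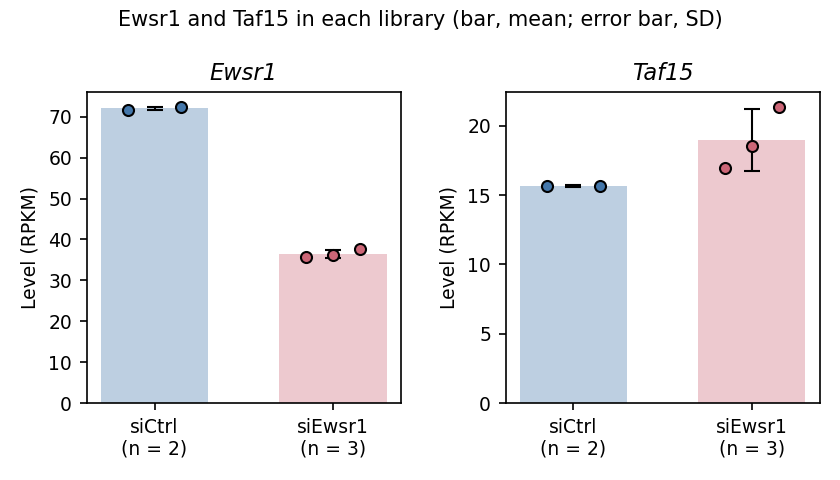
Levels of Ewsr1 and Taf15 in RPKM (y axis, from 0) in each siCtrl (n = 2) and siEwsr1 (n = 3) library; bars are group means, error bars SD and points single libraries. Ewsr1 lies at 71.7 and 72.3 RPKM in the siCtrl libraries and between 35.7 and 37.6 RPKM in the siEwsr1 libraries.

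Beyond Ewsr1, many genes differed between the groups, most by modest amounts. Large increases included that of E2f5, a transcription factor of the E2F family, and large decreases those of Banf2os, a transcript annotated as antisense, and Serpinh1, a collagen chaperone. Trib3, a stress-induced pseudokinase, fell from 54 ± 0.79 to 19.2 ± 5.15 RPKM, while the spliceosomal protein gene Snrpe rose from 61.6 ± 1.12 to 131 ± 10.2 RPKM. In all, 761 of 14925 genes (5.10%) were called by limma at an adjusted p under 0.05, 365 higher and 396 lower in siEwsr1, with a median absolute log2 fold change of 0.61. A change of at least 2-fold was found in 21 genes higher and 86 lower. The groups did not overlap in 5940 genes (39.8%), where chance gives 20% on average over splits of 2 libraries against 3. Genes share the same libraries, so a single split can lie far from 20%. An exact permutation test of 2 libraries against 3 cannot give a p below 0.1. The counts rested on single libraries: without siCtrl replicate 1 the test called 9 genes higher and 3 lower, without siCtrl replicate 2 it called 1 and 2, without siEwsr1 replicate 1 it called 36 and 46, and without siEwsr1 replicate 3 it called 1882 and 1899. The remaining fit, without siEwsr1 replicate 2, called 266 genes higher and 347 lower and kept 553 of the 761 calls. On the first principal component (45.1% of variance) the siCtrl libraries lay at -20.8 and -29.0 and the siEwsr1 libraries at 16.7, 34.3 and -1.22. Thus siEwsr1 replicate 3 stood nearest to the controls.

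**Figure D2:**
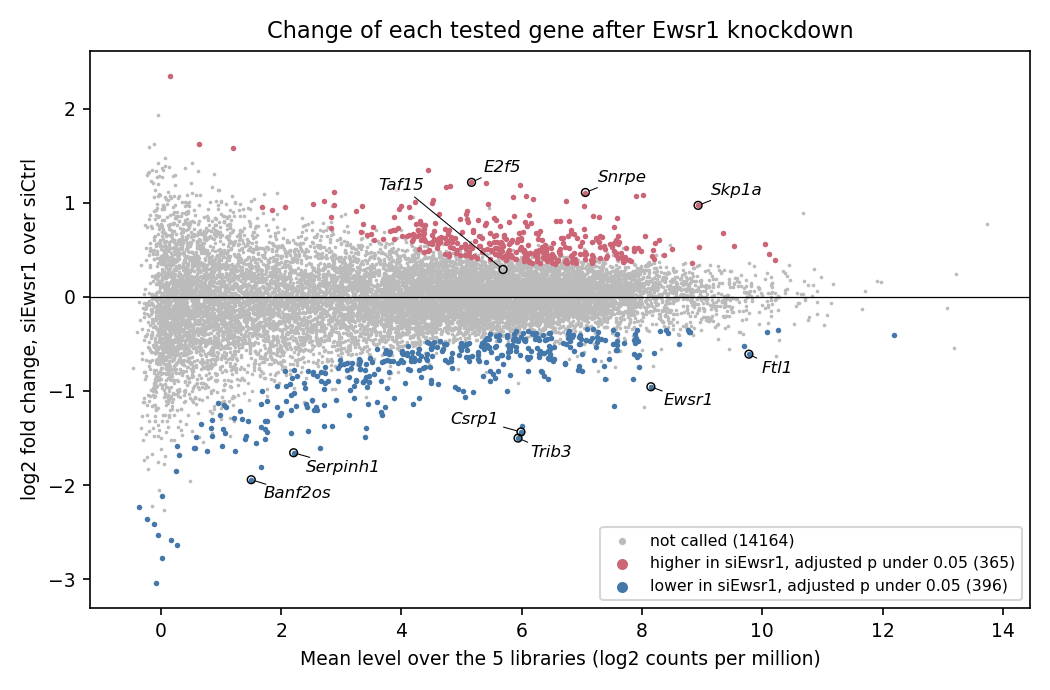
Log2 fold change of siEwsr1 over siCtrl (y axis) against the mean level over the 5 libraries in log2 CPM (x axis) for the 14925 tested genes. The 365 genes called higher and the 396 called lower are coloured, and 10 genes named in the text are circled, with Ewsr1 at -0.96.

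Among genes that rose, the 10 largest changes lay within a narrow range. E2f5 (chromosome 3, 14578641 to 14606309) rose from 12 ± 0.341 to 27.7 ± 2.30 RPKM, a log2 fold change of 1.22 (SE 0.12, adjusted p = 0.00106, limma). Smim15 (1.21), a small membrane protein gene, Rab5if (1.19), Ei24 (1.18), an endoplasmic reticulum protein gene induced by p53, and Sptssa (1.16), a subunit of serine palmitoyltransferase, followed. Praf2 (1.15), Snrpe (1.11), Api5 (1.08), an apoptosis inhibitor, Cyb5r4 (1.07) and Cd164 (1.07), a sialomucin, completed the set, with adjusted p from 9.02e-04 for Rab5if to 0.00489 for Praf2. The most abundant genes that rose included Skp1a (log2 fold change 0.97), a subunit of SCF ubiquitin ligases, Rnf4 (0.65), a ubiquitin ligase, Fkbp3 (0.60), a prolyl isomerase, and Api5. The 7-mer TCACTGC occurs in the annotated 3′ UTR of 6 of the 10 largest increases (E2f5, Smim15, Rab5if, Praf2, Api5 and Cd164) and in those of Skp1a and Rnf4. This 7-mer was picked from these same fold changes in a scan described below, so its presence here is not independent evidence. Of protein-coding genes not called higher, 12.7% carry it. Of the 10 largest increases, 4 were no longer called without siCtrl replicate 1 and 9 without siCtrl replicate 2 (adjusted p up to 0.146), whereas each stayed called without any 1 of the siEwsr1 libraries. Of the abundant genes, Fkbp3 also lost its call without siEwsr1 replicate 1 or 2 and Rnf4 without siEwsr1 replicate 1 (adjusted p up to 0.2). Skp1a, Rnf4 and Fkbp3 lost their calls without siCtrl replicate 1 (adjusted p up to 0.244), and without siCtrl replicate 2 so did these and Api5 (adjusted p up to 0.412).

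Among genes that fell, Csrp1 and Sept8 had the smallest adjusted p among named genes. Csrp1 (chromosome 1, 135720061 to 135752232), a LIM-domain protein gene, went from 59.1 ± 3.78 to 21.5 ± 1.04 RPKM, a log2 fold change of -1.44 (SE 0.09, adjusted p = 2.53e-04, limma), and Sept8 (chromosome 11, 53519257 to 53549565), a septin gene, from 18.9 ± 0.962 to 7.12 ± 0.351 RPKM, a log2 fold change of -1.37 (SE 0.09, adjusted p = 2.53e-04). Both carry the 7-mer GCAATTT in the 3′ UTR, which the other 8 of the 10 largest decreases do not (Banf2os has no annotated 3′ UTR). GCAATTT was likewise picked from these fold changes, and 7.41% of protein-coding genes not called lower carry it. Banf2os fell by 1.94 on the log2 scale, Serpinh1 by 1.66, Trib3 (chromosome 2, 152337422 to 152344032) by 1.5, and Adm2, the gene of a secreted peptide hormone, by 1.49. Dglucy (-1.44), Slc12a8 (-1.37), Cmya5 (-1.32) and Igsf23 (-1.32) were low genes, at 0.513 to 2.51 RPKM in siCtrl. Their log2 fold changes depend on the pseudocount: with a pseudocount of 1 they were -0.78, -0.87, -0.40 and -0.80, and over all alternatives they reached -1.60, -1.49, -1.83 and -1.54. How strand was handled in counting is not given, so the value of Banf2os may include reads of another gene on the opposite strand. The most abundant genes that fell were Ftl1, the ferritin light chain (852 ± 67.8 to 554 ± 91.4 RPKM, log2 fold change -0.61), Phgdh, the first enzyme of serine synthesis (-0.75), the type IV collagen gene Col4a1 (-0.62), the helicase gene Ascc3 (-0.60), which carries TCACTGC although it fell, and Ewsr1. Of the 10 largest decreases, 8 lost their call without siCtrl replicate 1 and the same 8 without siCtrl replicate 2 (adjusted p up to 0.362), with Csrp1 and Sept8 kept, and without siEwsr1 replicate 1 Cmya5 and Igsf23 lost theirs (adjusted p up to 0.130). Ftl1, Ascc3, Phgdh and Col4a1 were not called without siCtrl replicate 1, siCtrl replicate 2 or siEwsr1 replicate 1 (adjusted p up to 0.370).

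The list of unfolded protein and integrated stress response genes was lower after transfection with siEwsr1. Of 29 tested members, 15 fell, 1 rose and 13 were not called, and adjusted over the list alone 19 fell and 1 rose. Atf4, the central transcription factor of the integrated stress response, fell from 438 ± 2.54 to 302 ± 24.4 RPKM (log2 fold change -0.52, SE 0.09, adjusted p = 0.0114, limma). The other members that fell were Trib3 (-1.5), Cth (-1), Chac1 (-1), Ddit3 (-0.86), which encodes CHOP, Nupr1 (-0.79), Sesn2 (-0.79), Slc7a11 (-0.78), Phgdh (-0.75), Atf3 (-0.68), Xbp1 (-0.56), Herpud1 (-0.56), Ppp1r15a (-0.52), Sdf2l1 (-0.47), a folding gene, and Asns (-0.35). Edem1 (0.36) rose. The genes Aars (-0.37), Slc3a2 (-0.30), Psat1 (-0.29), Mthfd2 (-0.28) and Shmt2 (-0.26) did not pass the test, with adjusted p from 0.0652 to 0.279, nor did Dnajb9 (0.29, adjusted p = 0.202). The chaperone and folding genes Hspa5 (-0.07), Canx (-0.06), Calr (0.00), Pdia4 (0.02), Dnajc3 (0.07), Hsp90b1 (0.08) and Pdia6 (0.08) were not called, with adjusted p from 0.633 to 0.996. No test compared these subsets of the list. The median log2 fold change of the list was -0.37, at -0.39, -0.52 and -0.33 in siEwsr1 replicates 1, 2 and 3 against the control mean and at 0.02 between the controls. Camera gave adjusted p = 1.84e-08, and adjusted p = 0.655 with an estimated correlation. Of the called members, Slc7a11 carries GCAATTT and Edem1 carries TCACTGC in the 3′ UTR. Edem1 kept its call only without siEwsr1 replicate 3. Members called lower numbered 13 without siEwsr1 replicate 2 and 20 without siEwsr1 replicate 3. The list was called by camera without any 1 library, but the number of members called lower was 0 without siCtrl replicate 1, 0 without siCtrl replicate 2 and 4 without siEwsr1 replicate 1.

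**Figure D3:**
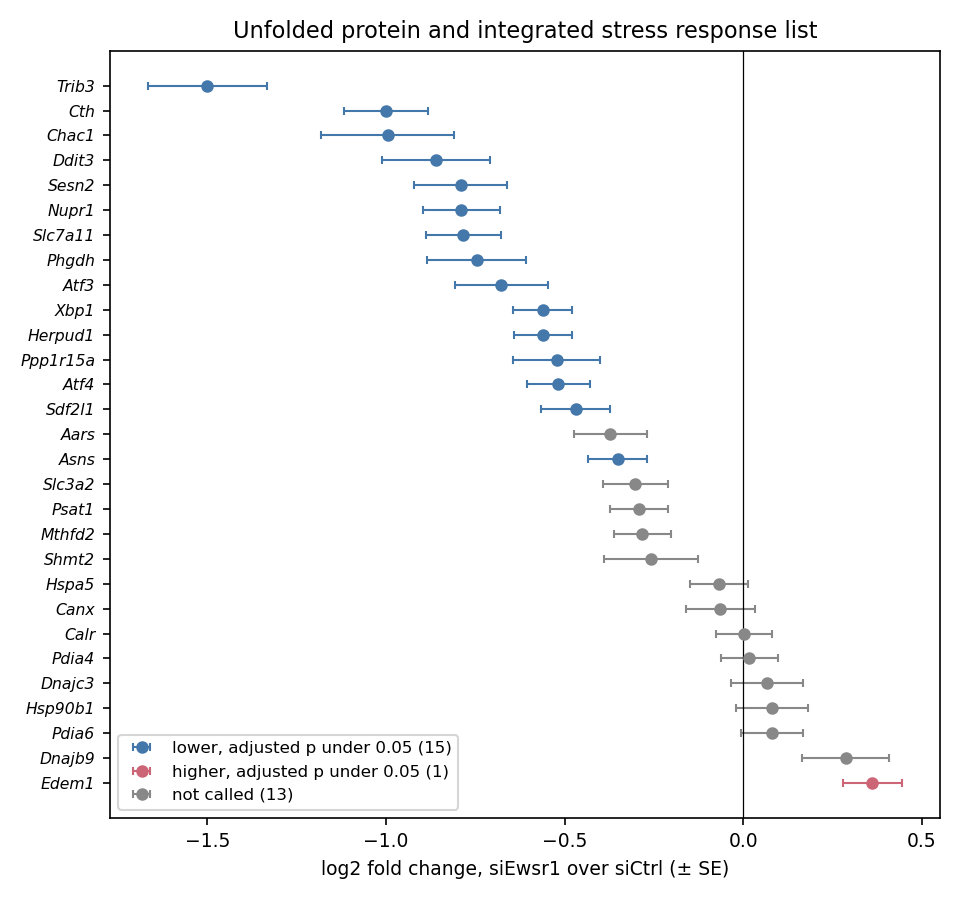
Log2 fold change of siEwsr1 over siCtrl with its SE (x axis) for the 29 tested genes of the unfolded protein and integrated stress response list (y axis). The 15 genes called lower reach from Asns at -0.35 to Trib3 at -1.5, and Edem1 is the 1 gene called higher.

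Extracellular matrix and TGF-beta target genes were lower as a list as well. Of 20 tested members, 6 fell and none rose, and adjusted over the list alone 8 fell. The basement membrane genes Lamc1 (log2 fold change -0.88, adjusted p = 0.00124, limma), Col4a2 (-0.67) and Col4a1 (-0.62) fell, as did Sparc (-0.54), a matricellular protein gene, the metalloproteinase inhibitor gene Timp2 (-0.68) and Vim (-0.37), the vimentin gene. Lamc1 and Timp2 carry GCAATTT in the 3′ UTR. The list median was -0.42, with -0.41, -0.45 and -0.31 in the siEwsr1 libraries against the control mean and 0.08 between the controls. Camera gave adjusted p = 1.76e-04, and adjusted p = 0.295 with an estimated correlation. The separate list of fibroblast and mural cell markers had a median of -0.37 but was not called (camera adjusted p = 0.0849). The number of members called lower was 0 without siCtrl replicate 1, 0 without siCtrl replicate 2, 1 without siEwsr1 replicate 1 and 10 without siEwsr1 replicate 3.

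DNA replication genes were higher. Of the 34 tested members of the DNA replication and S phase list, 8 rose and none fell, 14 rose adjusted over the list alone, and 32 had a log2 fold change above 0. E2f1 (0.83), Ccne1 (0.69), the cyclin E gene, Rfc5 (0.68), a clamp loader subunit, the helicase subunit genes Mcm7 (0.49), Mcm5 (0.47) and Mcm6 (0.44), Cdc45 (0.44) and Rrm2 (0.43), a ribonucleotide reductase subunit, rose. Rfc5 and Mcm5 carry TCACTGC in the 3′ UTR. The list median was 0.24, and 0.27, 0.24 and 0.24 in the siEwsr1 libraries against -0.02 between the controls. Camera gave adjusted p = 3.27e-10, and adjusted p = 0.134 with an estimated correlation. Of the homologous recombination and DNA damage signalling list (27 members, median 0.18), Atm (0.85), Brca2 (0.57) and Fanca (0.48) rose, 7 rose adjusted over the list alone, and camera gave adjusted p = 9.51e-04, and adjusted p = 0.655 with an estimated correlation. The counts of members called higher in these 2 lists were 0 and 0 without siCtrl replicate 1, 0 and 0 without siCtrl replicate 2, 1 and 1 without siEwsr1 replicate 1, and 18 and 12 without siEwsr1 replicate 3.

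Replication-dependent histone genes, whose messages lack a poly(A) tail, had a median log2 fold change of -0.44 over 65 tested members. Hist1h2ai (-0.80), Hist1h2bp (-0.76), Hist2h3b (-0.61), Hist1h2ag (-0.57) and Hist3h2ba (-0.35) fell, none rose, and 5 fell adjusted over the list alone. Camera gave adjusted p = 4.56e-07, and adjusted p = 0.735 with an estimated correlation. The libraries were unequal: the median was -0.43, -0.72 and -0.08 in siEwsr1 replicates 1, 2 and 3 against the control mean, and the siCtrl libraries differed from each other by -0.33. Without siCtrl replicate 2 the median was -0.22, and without siEwsr1 replicate 2 it was -0.29. Histone genes are near-identical in sequence, and how reads that map to several of them were counted is not given, so single members are uncertain. No member was called without siCtrl replicate 1, siCtrl replicate 2 or siEwsr1 replicate 1, 1 was called without siEwsr1 replicate 2 and 16 without siEwsr1 replicate 3. Mitochondrial ribosomal RNA held 1.55% and 0.80% of reads in the siCtrl libraries and 1.66%, 2.42% and 1.67% in the siEwsr1 libraries. The 11 mitochondrially encoded messages, which moved the same way, had a median of 0.36 with no member called over all genes or adjusted over the list alone (mt-Nd1, 0.36, adjusted p = 0.102). Their median was 0.25, 0.50 and 0.24 in the siEwsr1 libraries against the control mean and 0.16 between the controls, and it was 0.24 without siCtrl replicate 2 and 0.21 without siEwsr1 replicate 2. Camera gave adjusted p = 0.00624 for them, adjusted p = 0.735 with an estimated correlation, adjusted p = 0.160 without siCtrl replicate 2, and adjusted p = 0.176 without genes whose decimal position was read above the lowest.

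**Figure D4:**
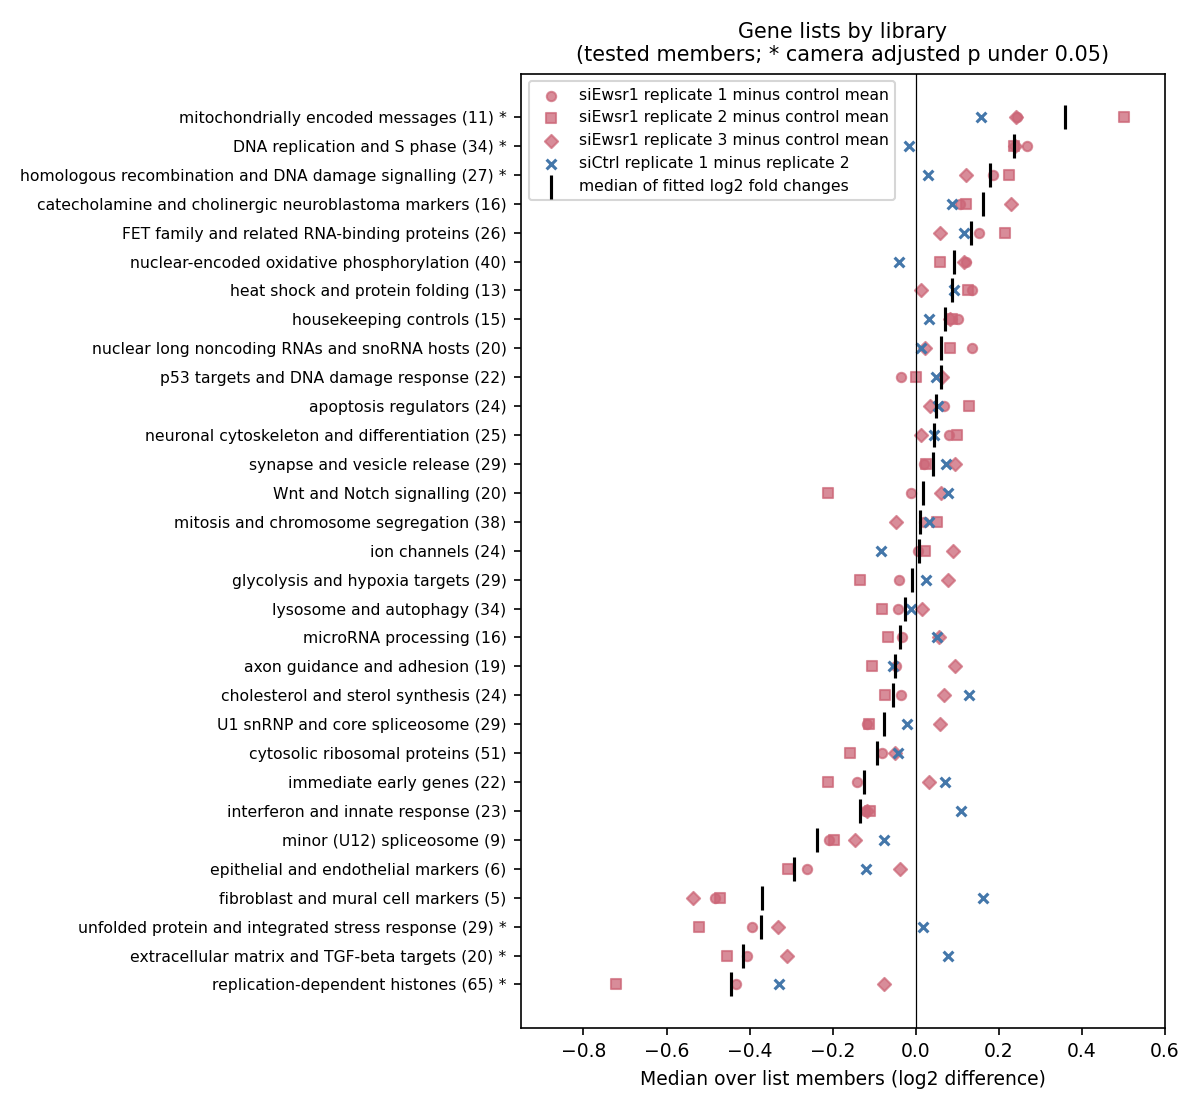
Median log2 difference over the tested members (x axis) of each of the 31 tested gene lists (y axis, number of members in brackets), for each siEwsr1 library against the control mean (red symbols), between the siCtrl libraries (blue crosses) and in the fit (black bars). Asterisks mark the 6 lists with a camera adjusted p under 0.05 at the preset correlation, which include the stress response list at -0.37 and the DNA replication list at 0.24.

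The remaining 25 tested lists were not called by camera. Their medians lay between -0.37 (fibroblast and mural cell markers) and 0.16 (catecholamine and cholinergic neuroblastoma markers), and the smallest adjusted p was 0.0697, for nuclear-encoded oxidative phosphorylation. Of the 6 lists called at the preset correlation, none holds with an estimated correlation. Fry gave an adjusted p under 0.05 for 2 of them, DNA replication (0.00829) and extracellular matrix (0.0396), and not for the stress response (0.0571), homologous recombination (0.0702), histone (0.336) and mitochondrial (0.336) lists. Median, mean and test differ in sign for microRNA processing, sterol synthesis, Wnt and Notch signalling and apoptosis regulators, all with medians within 0.0535 of 0. Single members of these lists passed the test over all genes. Of the RNA-binding protein list (26 members), Pspc1 (0.61) and Hnrnph1 (0.39) rose, and Ewsr1, Ddx17 (-0.47) and Hnrnpa3 (-0.39) fell. Of the core spliceosome list (29 members), Snrpe (1.11) rose and Snrpa1 (-0.79) fell. Lin28a (0.42) rose and Tnrc6a (-0.40) fell among 16 microRNA processing genes. Of 16 neuroblastoma markers, Isl1 (0.84) and Mycn (0.47) were among those that rose. The neuronal filament gene Ina (0.69) and the granin gene Chgb (0.45) rose, and Cplx2 (-0.91), a complexin gene of vesicle release, fell. Vegfa (-0.50), Sqstm1 (-0.50), Klf6 (-0.74), Wnt5a (-0.77) and Bak1 (-0.75) fell. Adjusted over the list alone, 6 RNA-binding protein genes rose and 4 fell, and 4 neuroblastoma markers rose and 1 fell. The 3′ UTRs of Ddx17, Isl1, Mycn, Ina and Wnt5a carry TCACTGC and that of Hnrnpa3 carries GCAATTT. Over the members of all lists, 26 genes were called higher and 43 lower; these counts were 2 and 1 without siCtrl replicate 1, 0 and 0 without siCtrl replicate 2, 5 and 10 without siEwsr1 replicate 1, and 124 and 167 without siEwsr1 replicate 3.

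Of the fibroblast and mural cell markers, 5 were tested and Acta2, the smooth muscle actin gene, fell from 2.76 ± 0.182 to 0.857 ± 0.0692 RPKM. Adjusted over the list alone, 3 fell (Acta2, Pdgfrb and Fbln1). The list median was -0.48, -0.47 and -0.54 in the siEwsr1 libraries against the control mean and 0.16 between the controls, and no member was called without siCtrl replicate 1, siCtrl replicate 2 or siEwsr1 replicate 1. The 6 tested epithelial and endothelial markers had a median of -0.29 with no member called. Of glial markers 4 genes reached the filter, none called (Mbp, adjusted p = 0.212), and of macrophage markers Cd68 and Tmem119 did, with log2 fold changes of 0.09 and 0.41 and neither called. Of 15 housekeeping controls, Actb (-0.41) fell and Tfrc (0.53), which carries TCACTGC, was among those that rose, with a list median of 0.07. The 22 p53 targets gave Ei24 higher and Sesn2 lower, and the 23 interferon response genes gave Mx2 (-1.81, annotated as a polymorphic pseudogene) and Ddx58 (-0.73) lower, with Ifit1 at 1.59 not called (adjusted p = 0.0627). Without siCtrl replicate 2 no member of any list was called, and without siCtrl replicate 1 the test called 3 list members.

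By annotated class, small nuclear RNA (snRNA) had the lowest median among classes with over 10 tested genes. Of 32 tested snRNA genes, 9 fell and none rose, and their median log2 fold change was -0.75. Summed over copies, U2 genes went from 93.4 ± 2.78 to 47.7 ± 8.09 CPM (counts scaled to the library total), U5 genes from 37.7 ± 2.30 to 19.6 ± 4.47 and U1 genes from 13.2 ± 0.449 to 7.4 ± 0.815, and each siEwsr1 library lay below both siCtrl libraries. U12 (Rnu12, log2 fold change -0.77, adjusted p = 0.0407, limma) fell, and U11 (-0.70) was not called. The 11 other snRNA genes had a median of 0.33 with none called, and their sum was 15.5 and 15.5 CPM in the siCtrl libraries and 18.7, 37.5 and 15.1 CPM in the siEwsr1 libraries. Copies of an snRNA are near-identical, so the division of reads among them is uncertain. Of 458 lincRNA genes, 22 fell and 4 rose. The share of reads in lincRNA genes overlapped between the groups, at 1.68% and 2.03% in siCtrl and 1.29%, 1.23% and 1.74% in siEwsr1. Of 11979 protein-coding genes, 351 rose and 345 fell, with a median of 0.00. Without siCtrl replicate 1 and without siCtrl replicate 2 no snRNA or lincRNA gene was called lower. These counts were 3 and 2 without siEwsr1 replicate 1, and 14 and 50 without siEwsr1 replicate 3.

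Gene length was nearly unrelated to the change. Across 14921 genes, Spearman's rho between genomic span and log2 fold change was -0.03, at -0.02, -0.04 and -0.05 in siEwsr1 replicates 1, 2 and 3, while the difference between the siCtrl libraries gave 0.08. Genes are not independent replicates, so no test was made. In the longest quintile of genes, with a median span of 105 kb, 70 genes rose and 134 fell, and their median log2 fold change was -0.03. In the shortest quintile, with a median span of 1.75 kb, 31 rose and 46 fell, with a median of -0.01.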

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

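The pseudocounts, no rescaling, the removal of solved-length or raised-reading genes, the odds limit of 1000 and the removal of genes with a 3′ UTR 7-mer were chosen after the data were seen. All other settings were planned. The planned DESeq2 alternative and the planned count-model versions of the other settings were not run. A count model could have been fitted to the inferred reads, but count models were kept for deposited counts; limma versions took their place, with limma-voom on the inferred reads. Ewsr1 kept its direction in 20 of 20 alternatives and its call in 19, and none of the 28 other named genes that were called reversed. Median-of-ratios scaling, the upper quartile, the strict filter, limma-voom, no robust moderation and the gene class restrictions moved no count of calls by over 1.5 times. Counts below are genes called higher and lower, then those of at least 2-fold.

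Without a filter, which raises the number of genes tested from 14925 to 27056, 20 and 42 genes were called, 12 and 29 at 2-fold, 4 snRNA and 2 lincRNA genes were called lower, and 5 lists were called higher. An adjusted p under 0.01 left 72 and 79 genes. A pseudocount of 1 gave 167 and 200 (13 and 18 at 2-fold, 4 snRNA genes lower), and a pseudocount of 0.01 gave 33 genes higher at 2-fold. Without genes carrying either 7-mer, 152 and 196 genes were called (11 and 53 at 2-fold), 5 snRNA genes were lower and 5 lists higher. With an estimated correlation 0 lists were called higher and 0 lower. The causes were not tested.

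Leaving out 1 library, the genes called higher ranged from 1 to 1882 and lower from 2 to 1899, at 2-fold from 1 to 83 and from 2 to 195, snRNA genes lower from 0 to 14, lincRNA genes lower from 0 to 50, and lists called higher from 2 to 5. The Ewsr1 level (log2 fold change) ranged from -0.97 to -0.94, and its adjusted p rose to 0.0568 without siCtrl replicate 2. Without a siCtrl library 1 control is left, assumed to vary like the siEwsr1 group. Without siEwsr1 replicate 3, 760 of the 761 genes stayed called. The cause was not tested.

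With the replicate number as a block, 1619 and 1598 genes were called (92 and 207 at 2-fold), with 14 snRNA and 49 lincRNA genes lower. Replicate number 3 exists only in siEwsr1, so the block takes siEwsr1 replicate 3 out of the comparison. The fit without that library called 1882 and 1899 genes, so the rise in calls cannot be credited to pairing. Deviations of same-numbered libraries correlated at 0.05 for number 1 and -0.13 for number 2, so the numbers were not taken to pair the libraries. Depth limits rare RNA most, since genes under 10 reads at the median library size were not tested.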

Other observations

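The tests of 7-mer selection, of stress genes without the 7-mer, of the stress list in each library, of short RNA recovery and of the summed snRNA copies were chosen after the result was seen. The tests of base composition, the Ewsr1 seed, matched random lists and snRNA by library were written before.

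Among small noncoding RNA outside the spliceosome, chosen after the values were seen, Snord118 (U8, needed for ribosomal RNA processing) fell by 1.38 on the log2 scale (90.7 ± 28.5 to 34.1 ± 8.08 RPKM, adjusted p = 0.0149, limma) and Snord13 (U13) fell by 0.89 (140 ± 11.7 to 74.5 ± 6.91 RPKM, adjusted p = 0.0125). Both have their own promoters, unlike most snoRNA. Snora2b also fell (-1.17) and Snora73b rose (0.86). Rn7sk, the 7SK RNA, had a log2 fold change of -0.13 (adjusted p = 0.778).

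In a scan of 15627 3′ UTR 7-mers over 10795 protein-coding genes, adjusted for UTR length, GC content and level, the 891 genes with GCAATTT had a mean residual of -0.12 (z -12.7) and the 1519 genes with TCACTGC one of 0.09 (z 12.1), where 7-mers sharing no 5 bases with either stayed between -3.84 and 3.82. GCAATTT occurs in 24.7% of 344 genes called lower against 7.41% of the others (Fisher's exact p = 3.57e-22, two-sided, across genes), and TCACTGC in 38.3% of 350 genes called higher against 12.7% (p = 3.00e-32), while genes called higher carried GCAATTT less often (4% against 8.03%, p = 0.0046) and genes called lower carried TCACTGC in 11.3% against 13.5% (p = 0.262). The 7-mers were picked from the fold changes of these same genes, so the Fisher p-values restate that selection. Those p-values also treat genes as independent replicates, which genes are not. The shift of GCAATTT genes was -0.14, -0.12 and -0.14 in the siEwsr1 libraries and 0.01 between the controls. That of TCACTGC genes was 0.10, 0.11 and 0.10 against 0.00. Chance selection among genes is argued against by a split of the genes: the same 7-mers were picked in one part and shifted in the other. Both parts come from the same libraries, so the split cannot exclude a chance difference between the libraries. The permutation p was 1e-05, the smallest that 100000 permutations can give, and it too treats genes as independent. Other 7-mers of the same bases reached an absolute z of at most 5.42 for GCAATTT and 6.24 for TCACTGC. That 0 of them lay as far was fixed in advance, since both 7-mers are the extremes of the scan. Their smaller z shows only that the shift was not common to 7-mers of these bases. A candidate explanation for GCAATTT is the seed of the Ewsr1 siRNA acting like a microRNA: the 7-mer lies in 3 of 5 protein-coding Ewsr1 transcripts (chromosome 11, 5078547 to 5078553, coding part of exon 11 of 17 of the longest, in which 12.8% of all 7-mers occur; the isoform with the longest 3′ UTR lacks it in coding sequence and 3′ UTR), the shift grew from -0.13 with 1 site to -0.20 with more, and it was -0.04 for sites in coding sequence alone, while TCACTGC occurs in 0 of these transcripts and may belong to the control siRNA, whose sequence is not given in the sources used here.

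The fall of the stress response list was weighed against 3 technical explanations. Direct matches to GCAATTT in the 3′ UTR cannot account for most of the fall, since 14 of the 27 members without it were called lower, with a median of -0.35 (95% bootstrap interval over members -0.56 to -0.07). Level, transcript length and base composition are argued against by 10000 random lists matched on them, of which 0% had a median as low as -0.37 (lowest -0.19). A single siEwsr1 library does not account for it, as the highest median was -0.33. A single deviating control is argued against by the difference of 0.02 between the controls. A shift shared by both controls would not show in that difference. What stays open is whether the fall follows loss of Ewsr1, an effect of either siRNA or another difference between the groups. A single siRNA against Ewsr1 and a single control siRNA cannot separate these. Joint variation of the list's genes over few libraries is not excluded either. Camera with an estimated correlation gave adjusted p = 0.655 and fry adjusted p = 0.0571. That Ewsr1 knockdown lowers these genes may be held as a hypothesis. Another Ewsr1 siRNA with a different seed, or a rescue, would test it.

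The fall of snRNA was weighed in the same way. Lower recovery of short RNA was set against 63 snoRNA and scaRNA genes of like length. Their median log2 fold change was 0.24 (95% bootstrap interval 0.12 to 0.35), at 0.14, 0.50 and -0.01 in siEwsr1 replicates 1, 2 and 3 and 0.12 between the controls. The snRNA median was -0.75 (interval -0.85 to -0.46), at -0.70, -0.53 and -0.99 in the siEwsr1 libraries. Both intervals resample genes, and snRNA copies are near-identical, so the intervals do not measure the spread between libraries. The comparison therefore rests on the library medians. It cannot exclude lower recovery, since most snoRNA lack promoters of their own. Snord118 and Snord13, which have them, fell, while Rn7sk was not called. A different division of reads among the tested copies is argued against by their sum, which changed by -38.5% (194 ± 9.74 to 119 ± 27.8 CPM, no overlap). How reads that map to several genes were counted is not given. The sum therefore cannot tell whether such reads left the count. A single siEwsr1 library is argued against by the highest median of -0.53, next to a difference of 0.12 between the controls. An effect of Ewsr1 loss on snRNA level may be held as a hypothesis, to be tested with another Ewsr1 siRNA or a rescue. Effects of the siRNA sequences, lower recovery of short RNA and other differences between the groups are open. The 11 snRNA genes outside the U1, U2, U5, U11 and U12 families did not share the fall, with a median of 0.33.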
